A study of Drosophila melanogaster with 3 samples.

How the data were processed

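Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole white prepupae of Drosophila melanogaster that stably expressed Ets21C, an ETS-family transcription factor, with a C-terminal enhanced green fluorescent protein (eGFP) tag. Per the labels, the precipitation used an antibody against GFP, both sexes were pooled, and chromatin was sheared by sonication to a size range of 200 to 800 bp. There were 3 biological replicates, all of 1 group, so no comparison between groups and no pairing was made. No control or untagged library was among the samples analysed here.

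The deposited peak lists were used. Per the sample notes deposited with the lists, each replicate list was derived from that replicate's alignments and a control alignment. A pooled list was derived in the same way from the alignments of all 3 replicates, and an optimal list was derived from the replicate lists and the pooled list by the irreproducible discovery rate (IDR). The replicate and pooled lists are called relaxed below, since they hold weak calls as well as strong ones. The pooled list was labelled as peaks and background for IDR, and its lowest −log10 q was 0.0176. Comparisons with relaxed peaks are therefore with a mix of weak peaks and background. The aligner, the peak caller, their versions and the IDR settings are not given in the sources used here. The height of a peak is the signal value that the authors deposited with it. Signal values are on a scale of their own in each list, so they were ranked and compared within a list. Between replicates they were compared only after each was scaled to the median of its own highest peaks, as given below. The −log10 q values in the deposited lists were not used in any test. The lists hold no reads or counts, so the sequencing depth of each replicate is unknown here.

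Each list was deposited on 2 builds. The Release 6 lists (dm6) were the main ones, because the annotation used here, Ensembl release 115, is of that assembly, and every peak lay within the lengths of its sequences. The dm3 lists were used only for counts and, as alternatives, for the summits shared between lists and the share on X. No coordinate was converted. Coordinates are 1-based, and 17947 genes with 23773 TSS positions on the main arms were used. Annotation, base composition and words were analysed on 2L, 2R, 3L, 3R, 4 and X, which held 4482 of the 4505 optimal peaks. The other 23 were mitochondrial.

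The top list of a replicate was its 4505 peaks of highest signal, as many as in the optimal list. Summits within 100 bp were counted as shared, and shared percentages were tested one-sided against 1000 random shifts of the summits by 5 to 50 kb. A promoter peak had its summit within 500 bp of an annotated TSS. Its share was compared by a two-sided Fisher's exact test with 22003 peaks of the pooled relaxed list that lay over 500 bp from any optimal summit. A promoter summit was counted at no other place, so exons, UTRs, introns and intergenic sequence hold only summits over 500 bp from a TSS. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 26 lists. Words on either strand within 100 bp of a summit were compared with windows of the same length centred 500 bp away, by a two-sided exact McNemar test against the upstream window, adjusted over 18 words. Heights were compared by two-sided permutation tests of the difference of medians with 100000 resamples. Peaks and genes are not independent replicates, so these p-values describe the lists and not the spread between animals. Values per replicate are given as mean ± SD. Exact (Clopper-Pearson) 95% intervals of percentages, and upper limits set by a count of 0, cover counting error only.

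The gene lists, words, tests and most alternatives were fixed before the data were examined. Of the listed symbols, those without a match to a protein-coding gene were left out. The genes named were the 25 with the highest promoter peak that was also in the top list of all 3 replicates (the nearest TSS per peak), Ets21C, and in each gene list up to 4 members with the highest promoter peak and up to 2 without one. Height per replicate is given relative to the median of that replicate's top list. Where a named peak is said to be found in fewer than 3 replicates, the whole replicate lists were counted. Those lists also hold peaks below the top lists.

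Alternatives covered the TSS window, the summit distance, the length of the top lists, the build, the background, the upper part of the list by signal, gene bodies in place of promoters, other word windows and each replicate left out in turn. With a replicate left out, only optimal peaks found in the top lists of both others were kept. These peaks and their signals still came from the optimal list, made with every replicate. Random positions and random gene lists matched on base composition were added after seeing the data, as were values with mitochondrial peaks kept and promoter heights over peaks found in all replicates.

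The statistics were tested on simulated data. With 4000 simulated peaks of which 40.0% lay at promoters, the promoter share came out at 40.0%. An overlap of 60.0% between simulated lists came out at 60.7%, and an ETS word planted in 20.0% of summits gave a difference of 20.0 percentage points. All 10 simulated gene lists with raised occupancy were called, and 0 of 20 unchanged lists. The simulated promoter share was set by where peaks were placed, so it checks the counting only. Simulated summits and flanks had the same base composition, so the effect of AT-rich summits on the word test was not covered. Simulated genes gained peaks independently of each other, of TSS number and of gene length, so false calls from those were not covered. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.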

Results

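Among the Ets21C-eGFP promoter peaks found in all 3 replicates of whole white prepupae, the stage at the onset of metamorphosis, the highest were at CG14100, Ugalt, CG1888, PNPase and Chro. The peak at CG14100 (FBgn0036889, 3L:19590413-19590836) had a signal of 4103, the highest of the 4505 optimal peaks, whose median was 192. The optimal peaks were the 4505 peaks of highest signal among the 27085 of the pooled list, and the replicate lists held 30000, 28006 and 30000 peaks. The top lists of replicates 2 and 3 shared 67.2% of their peaks, those of replicates 1 and 2 59.1%, and those of replicates 1 and 3 51.6%. The mean was 59.3%, against 1.02% for randomly shifted summits (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the optimal peaks, 2066 (45.9%, 95% interval 44.4 to 47.3%) were in the top lists of all 3 replicates, against 0.432% for shifted summits. Another 1531 were in exactly 2 top lists, 810 in 1 and 98 in none. Replicate 1 held 65.5% of the optimal peaks, replicate 2 80.2% and replicate 3 77.9% (mean 74.5 ± 7.90%, n = 3). The optimal list was made from these replicates, so this share is not independent of it.

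Promoters held 1805 of 4482 optimal summits on the nuclear arms (40.3%, 95% interval 38.8 to 41.7%), against 19.0% of 22003 other relaxed peaks (Fisher's exact p = 6.93e-190, adjusted over 7 places 4.85e-189) and 13.4% of random positions. The share was 55.4% among the 500 highest optimal peaks. The excess of 21.2 percentage points over relaxed peaks was 13.3 without replicate 2 and 13.5 without replicate 3. Introns held 40.9% of optimal summits and 44.9% of relaxed peaks, and intergenic sequence held 16.9% and 27.9%. Over 500 bp from a TSS, coding exons held 5 optimal summits (0.112%), against 2.47% of relaxed peaks and 13.7% of random positions. There 3' UTRs held 0.535% against 4.04%. In the top lists of replicates 1, 2 and 3 promoters held 26.1%, 43.9% and 48.9% of summits (39.6 ± 12.0%, n = 3). Among their 500 highest peaks the shares were 48.8%, 59.6% and 51.4%. An optimal promoter peak was present at 2118 of 13968 protein-coding genes (15.2%), and 1211, 2429 and 2594 genes had one in the top lists of the replicates (2078 ± 755, n = 3). With only the peaks shared by replicates 1 and 3, so without replicate 2, the count was 828, and without replicate 3 it was 905. Of 1683 promoter peaks at a coding gene, 616 (36.6%) lay near 2 or more such genes, so the gene that a peak acts on is open there.

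**Figure D1:**
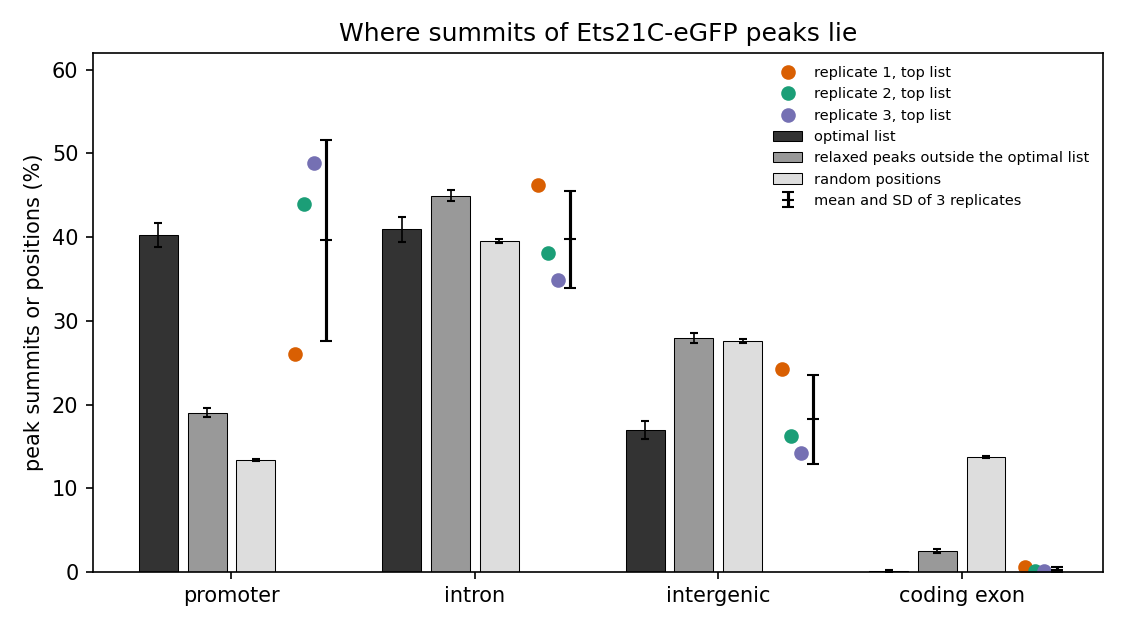
Places of peak summits. Percent of summits at each kind of place for the optimal list, the other relaxed peaks, random positions and the top list of each replicate.

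The 25 genes with the highest promoter peaks found in every replicate had signals of 1627 to 4103, and at 20 of them the summit lay upstream of the TSS. Heights below are multiples of the median of each replicate's top list (mean ± SD, n = 3). CG14100 had a height of 22.9 ± 6.92, 85 bp upstream of its TSS. Ugalt (FBgn0024994, X:2703683-2704100), which encodes a UDP-galactose transporter, had 16.2 ± 3.61, with its summit 39 bp upstream. PNPase (FBgn0039846, 3R:31404470-31404868), a polynucleotide phosphorylase, had 13.6 ± 2.71. Chro (FBgn0044324, 3L:22878689-22879120), a chromodomain protein of interbands and the spindle matrix, had 13.9 ± 3.32. The polycomb-group gene ph-p (FBgn0004861, X:2137181-2137554) had 10.9 ± 3.33, its summit 476 bp upstream. Sox14 (FBgn0005612, 2R:23978374-23978755), an ecdysone-induced transcription factor, had 10.6 ± 3.08, and Shc (FBgn0015296, 3L:9426693-9427080), an adaptor of receptor tyrosine kinases, had 10.3 ± 3.70. The translation factor gene eIF6 had 9.19 ± 2.49. The mitochondrial ribosomal protein gene mRpL41 had a signal of 2141. The peaks named for CenG1A (2L:13835267-13835640) and Art3 (3R:15229332-15229733) were also the promoter peaks of mRpS23 and mRpS10, with signals of 2368 and 2247. Signals at the other genes were 2779 at CG1888, 2468 at Tcs5, 2298 at larp, 2025 at CG31145, 1797 at Pal1, 1745 at GstE13, 1739 at Trp1, 1735 at CG9147, 1722 at CG18549, 1696 at CG8320, 1669 at CG8360, 1669 at CG5098, 1638 at CG3552 and 1627 at CG13921.

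Ecdysone-response genes and genes of AP-1, ATF and other bZIP factors had promoter peaks more often than other genes in the optimal list and in each replicate. Of 35 ecdysone-response genes, 16 had one (45.7%, 3.03-fold, Fisher's exact test with Benjamini-Hochberg adjusted p = 1.09e-04), with 10, 15 and 16 in the replicates (adjusted p = 0.00622, 0.00196 and 0.00139). Besides Sox14, peaks lay at hid, a cell death gene (signal 714), at Hr3, a nuclear receptor (633), and at E23, an ABC transporter (611). Blimp-1 and Cth had none. Of 19 bZIP genes, 10 had one (52.6%, 3.48-fold, Fisher's exact adjusted p = 8.09e-04), with 7, 11 and 8 in the replicates (adjusted p = 0.00622, 5.35e-04 and 0.0435). They included REPTOR, which acts downstream of TORC1 (776), Irbp18 (621), Atf3, a stress-induced factor (475), and cnc, the Nrf2 homologue (392, found in 2 replicates), but not Atf-2 or Atf6. With a replicate left out fewer peaks remained (2308 without replicate 2, 2477 without replicate 3), and some calls were lost while the folds were no lower. Without replicate 2 the ecdysone list had 3.39-fold (Fisher's exact adjusted p = 0.0509) and the bZIP list 3.56-fold (0.101), and without replicate 3 the bZIP list had 4.08-fold (0.0530). With promoters narrowed to 250 bp the folds fell to 2.19 for the ecdysone list and 2.69 for the bZIP list, and neither passed (Fisher's exact adjusted p = 0.0685 for each). Among genes with a relaxed promoter peak they fell to 1.38 (0.354) and 1.73, and neither passed. Against genes matched on TSS number and length the ecdysone list fell to 1.71-fold (adjusted permutation p = 0.0609), and the bZIP list passed with 2.16-fold. Of 31 EGFR, Ras and MAPK genes, 11 had a peak (35.5%, 2.35-fold, Fisher's exact adjusted p = 0.0158), among them Shc, spi, an EGFR ligand (755), cic, a repressor under MAPK control (374), and Krn, another ligand (339), but not Cbl or Dsor1. This list passed in none of the replicates (6, 8 and 11 genes), and the fold was 1.49, 3.28 and 2.50 without replicates 1, 2 and 3 (Fisher's exact adjusted p = 0.699, 0.0647 and 0.153). It also did not pass with promoters of 250 bp (1.92-fold, Fisher's exact adjusted p = 0.221), among genes with a relaxed promoter peak (1.27-fold, 0.684) or among the peaks of higher signal (1.75-fold, 0.437). Nor did it pass against genes matched on TSS number and length (1.86-fold, adjusted permutation p = 0.140) or on base composition (2.11-fold, 0.0663).

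Cytosolic ribosomal protein genes had promoter peaks at 44 of 91 (48.4%, 3.24-fold, Fisher's exact adjusted p = 1.94e-12), but this came from replicates 2 and 3. The top lists of replicates 1, 2 and 3 had peaks at 7, 35 and 63 of these genes, and the fold was 0.555 without replicate 2 and 0.847 without replicate 3. Peaks at RpL32 (signal 695), RpS27 (515) and RpS20 (488) were found in 2 replicates, that at RpL34b (619) in all 3, and RpL10Aa and RpL10Ab had none. Mitochondrial ribosomal protein genes had peaks at 24 of 73 (32.9%, 2.18-fold, Fisher's exact adjusted p = 8.76e-04), with 11, 25 and 25 in the replicates, among them mRpL23 (1460) but not mRpL1 or mRpL10. It did not pass in replicate 1 (1.74-fold, Fisher's exact adjusted p = 0.193), nor without replicate 2 (2.09-fold, 0.146) or replicate 3 (2.13-fold, 0.114). Among the 2252 optimal peaks of higher signal neither ribosomal list passed: the cytosolic fold fell to 1.92 (0.0521), and the mitochondrial fold was 1.94 (0.0863). No peak lay at the promoters of 179 odorant, gustatory and ionotropic receptor genes, such as Gr10a and Gr10b (Fisher's exact adjusted p = 4.11e-12, a share under 1.68%), or of 70 Cpr cuticle protein genes, such as Cpr100A and Cpr11A (1.09e-04, under 4.29%). The receptor list passed with each replicate left out in turn, while the Cpr list did not pass in replicate 1 (1 gene, 0.157) nor, with 0 peaks in each case, without replicate 2 (0.101), without replicate 3 (0.0743) or among genes with a relaxed promoter peak (0.172).

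**Figure D2:**
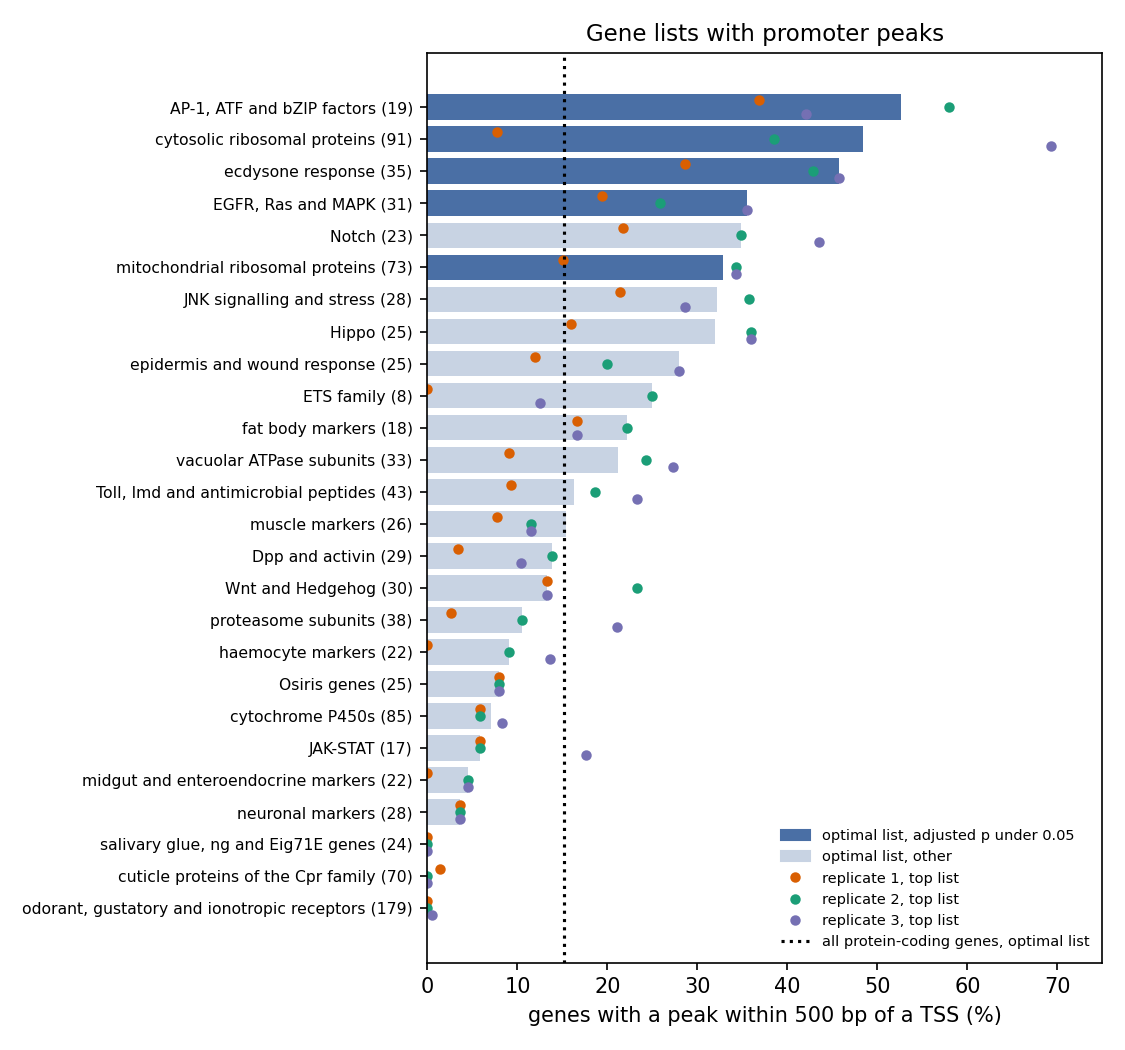
Promoter peaks in 26 gene lists. Percent of the genes of each list with an optimal promoter peak and with one in the top list of each replicate.

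The other 19 lists did not pass in the optimal list, though some did in single replicates. Genes of the P450 list had fewer peaks than other genes in replicates 2 (0.337-fold, Fisher's exact adjusted p = 0.0133) and 3 (0.442-fold, 0.0420). Salivary glue genes had 0 in both (Fisher's exact adjusted p = 0.0478 and 0.0435), and Notch genes had more in replicate 3 (2.35-fold, 0.0224). JNK and stress genes had peaks at 9 of 28 (Fisher's exact adjusted p = 0.0831): at Mkk4, a kinase that activates JNK (signal 1375), at hid, at Atf3 and at puc, the JNK phosphatase (242, found in 2 replicates), but not at Ask1. Notch genes had 8 of 23 (0.0523), with E(spl)m3-HLH (580), aph-1 (483), numb (409) and E(spl)m7-HLH (318) but not Brd or E(spl)m5-HLH. Hippo genes had 8 of 25 (0.0937), with app (415), Mer (322), mats (302) and ft (232) but not Diap1 or Myc. Epidermis and wound genes had 7 of 25 (0.178), with grh (309), sqh (230) and shot (182) but not Cad96Ca or Ddc. With promoters widened to 1000 bp the JNK, Notch, Hippo, epidermis, P450 and salivary glue lists passed. Over gene bodies and 2 kb upstream the same lists passed, as did Dpp and activin (2.50-fold, Fisher's exact adjusted p = 2.34e-04) and Wnt and Hedgehog genes (1.84-fold, 0.0304). That test was not adjusted for gene length, and long genes have more room for peaks: shn, of 58309 bp, had 14. At promoters the Dpp and activin list had 0.909-fold. Against genes matched on TSS number and length, none of these lists passed at promoters. Of 8 ETS-family genes, Eip74EF (260) and aop (142) had a peak, each found in 2 replicates, and Ets65A had none (0.503). Toll and Imd genes had 7 of 43 (0.939), with imd (671), cact (607), Traf6 (235) and GNBP3 but not AttA or AttB. JAK-STAT genes had 1 of 17 (0.646), Ptp61F (151), and Socs36E and Socs44A had none. Wnt and Hedgehog genes had 4 of 30 (1.00), sgg (901), fz3 (250), nkd (240) and lgs (134), with none at Apc or Apc2. Dpp and activin genes had 4 of 29 (1.00), dlp (222), cv (149), Dad (122) and shn, with none at Actbeta or Mad. Muscle genes had 4 of 26 (1.00), Msp300 (1365), Tm1 (198), sls (186) and mys (141), with none at Act57B or Act79B. Fat body genes had 4 of 18 (0.503), bmm (217), FASN1 (210), Lip3 (182) and Lsd-2 (125), with none at AkhR or Fbp1. Haemocyte genes had 2 of 22 (0.697), PPO3 (165) and mys, with none at Col4a1 or He. Neuronal genes had 1 of 28 (0.206), elav (758), with none at Appl or CadN. This list passed as having fewer peaks against genes matched on TSS number and length (0.129-fold, adjusted permutation p = 0.0177, from random lists) and among genes with a relaxed promoter peak (0.160-fold, Fisher's exact adjusted p = 0.0422). Midgut genes had 1 of 22 (0.409), Myo61F (114), with none at AstA or AstC. Proteasome genes had 4 of 38 (0.767), Rpn5 (547), Rpn3 (330), Rpn6 (214) and Rpn11 (177), with none at Prosalpha1 or Prosalpha1R. Vacuolar ATPase genes had 7 of 33 (0.503), with Vha100-2 (841), Vha16-5 (249), Vha16-1 (231) and Vha55 (178) but not Vha100-1 or Vha100-3. The cytochrome P450 list had 6 of 85 (Fisher's exact adjusted p = 0.0871), with Cyp6u1 (663), Cyp310a1 (529), Cyp6v1 (301) and Cyp317a1 (173) but not Cyp12a4. This list also held Cyp1, a cyclophilin gene and not a P450, which had no peak, so its size overstates the number of P450 genes. Osiris genes had 2 of 25 (0.566), Osi24 (194) and Osi2 (150), with none at Osi1 or Osi10a. The 24 salivary glue, ng and Eig71E genes had 0 (0.0937, a share under 12.5%), Eig71Ea and Eig71Eb among them. Of the peaks named in these lists, those at shn, shot, Lsd-2 and Rpn3 were found in the whole list of only 1 replicate. Those at imd, Traf6, Mer, mats, dlp, cv, Dad, lgs, Lip3, Tm1 and mys were found in the whole lists of 2 replicates, though not always in their top lists. So were those at PPO3, Rpn6, Rpn11, Vha16-5, Vha16-1, Vha55, Myo61F and Cyp317a1. The peaks at bmm and sqh were in the whole lists of all 3 replicates but not in all 3 top lists.

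The ETS word CCGGAAGY lay within 100 bp of 13 optimal summits (0.290%, 95% interval 0.155 to 0.495%), against 0.513% of flanks (exact McNemar adjusted p = 0.159). It was no more frequent at summits in any replicate: 0.223%, 0.290% and 0.468% (0.327 ± 0.127%, n = 3), with 0.599 ± 0.0228% in flanks. The shorter core MGGAAR was rarer at summits than in flanks (28.2% against 34.2%, adjusted p = 9.68e-09), and rarer than at random positions matched on base composition (33.2%, Fisher's exact adjusted p = 5.83e-10). The DRE word TATCGATA, the site of the insulator and promoter factors DREF and BEAF-32, lay at 111 summits (2.48% against 0.547%, 4.53-fold, exact McNemar adjusted p = 3.02e-14), and at 0.831% of matched positions (1.30e-16). The M1BP word GGTCACACT, found in promoters of ribosomal protein genes, lay at 36 (0.803% against 0.290%, 6.54e-05), and at 0.255% of matched positions (2.11e-06). In replicates 1, 2 and 3 the DRE word lay at 1.03%, 2.70% and 4.30% of summits and the M1BP word at 0.380%, 0.938% and 1.52%. Matched positions were not matched on distance to a TSS: promoters held 40.3% of the optimal summits but 15.0% of matched positions. Whether the DRE and M1BP words were more frequent than at promoters in general was not tested. The GATA word lay at 29.4% of summits, 1.47-fold the share of flanks (3.02e-27), but at 28.9% of matched positions (0.976). GAGA (2.48% against 5.21%), Brinker (10.5% against 22.3%), E-box (1.74% against 2.47%), Scalloped (3.99% against 4.83%) and 2 rearrangements of the ETS letters (0.446% against 1.03%, 0.826% against 2.16%) were rarer at summits than in flanks, but not rarer than at matched positions, and GAGA was more frequent than there (1.88%, Fisher's exact adjusted p = 0.0409). Matching was chosen after the data were seen. AP-1 (1.70% against 2.10%, exact McNemar adjusted p = 0.310), STAT (5.89% against 5.22%, 0.131), Zelda (2.12% against 2.82%, 0.0738), grainy head (0.134% against 0.379%, 0.108), NF-kB (1.23% against 1.72%, 0.0840) and the other rearrangement (0.535% against 0.658%, 0.526) did not pass, and the ecdysone half-site pair lay at 0 summits. Against matched positions STAT was rarer at summits (5.90% against 7.12%, Fisher's exact adjusted p = 0.0134), and the other rearrangement, AGCGCAYG, a control word, was more frequent (0.536% against 0.299%, 0.0495).

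Optimal summits were AT-rich. Bases G and C made up 32.4 ± 7.67% (mean ± SD over 4482 peaks) of the sequence within 50 bp of a summit and 44.0% of the flanks, with fewer at the summit in 3847 peaks (85.8%). Promoter peaks had 33.2%, other optimal peaks 31.9%, the 500 highest 30.6%, relaxed peaks 35.9% and random positions 42.0%. The replicates had 32.4%, 31.6% and 34.9%. The 13 peaks with the ETS word had a median signal of 174, against 192 without it (two-sided permutation p = 0.597). With a window of 50 bp the order turned round (60.3 higher, 4 peaks, permutation p = 0.542). Promoter peaks had a median signal 24.7 above the 182 of other optimal peaks (two-sided permutation p = 2e-05, the smallest that 100000 resamples can give). That difference was 33.8 without replicate 1, 83.6 without replicate 2 and 74.3 without replicate 3. Leaving out a replicate changed only which peaks were kept, and the signals were still those of the optimal list.

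**Figure D3:**
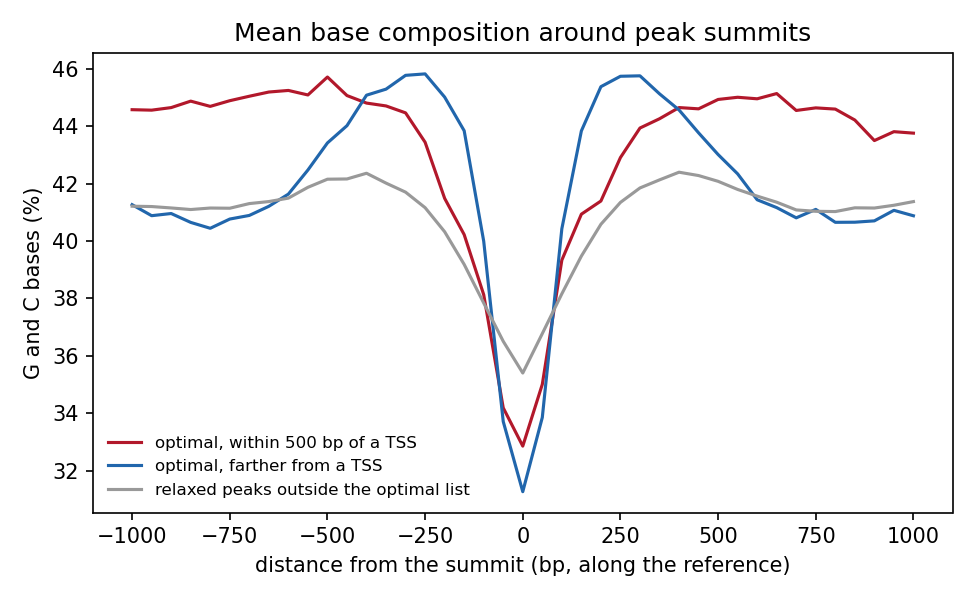
Base composition around summits. Percent of G and C by distance from the summit for optimal peaks within 500 bp of a TSS, optimal peaks farther from a TSS, and relaxed peaks outside the optimal list.

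The X chromosome held 897 of 4482 optimal peaks (95% interval of the share 18.9 to 21.2%), against 16.9% of other relaxed peaks (Fisher's exact adjusted p = 1.76e-06) and 17.6% of the length of the arms. The top lists of replicates 1, 2 and 3 had 19.3%, 16.1% and 20.2% on X. The difference of 3.15 percentage points between optimal and relaxed peaks was 2.14 without replicate 1, 6.23 without replicate 2 and 4.05 without replicate 3. The fourth chromosome held 14 optimal peaks (0.312% against 1.58%, Fisher's exact adjusted p = 1.13e-13), and 3R held 22.8% against 24.6% (0.0304).

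Ets21C itself (FBgn0005660, 2L:544925-552923) had no optimal promoter peak. Of the optimal peaks, 2 lay within 20 kb of the gene (highest signal 194) and 6 within 50 kb (447), all in the neighbouring gene ush, which encodes a GATA cofactor. The nearest pooled summit to its TSS was 22378 bp away. The pooled list had no peak in 2L:527324-602339, which held 15 coding genes, Ets21C, rempA, Gsc and Ptth among them. Within 20 kb of Ets21C replicates 1, 2 and 3 had 0, 6 and 4 peaks. A summit in ush at 2L:530428 was peak 108 of replicate 2 by signal, and one at 2L:530432 was peak 95 of replicate 3, with no pooled peak within 500 bp.

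**Figure D4:**
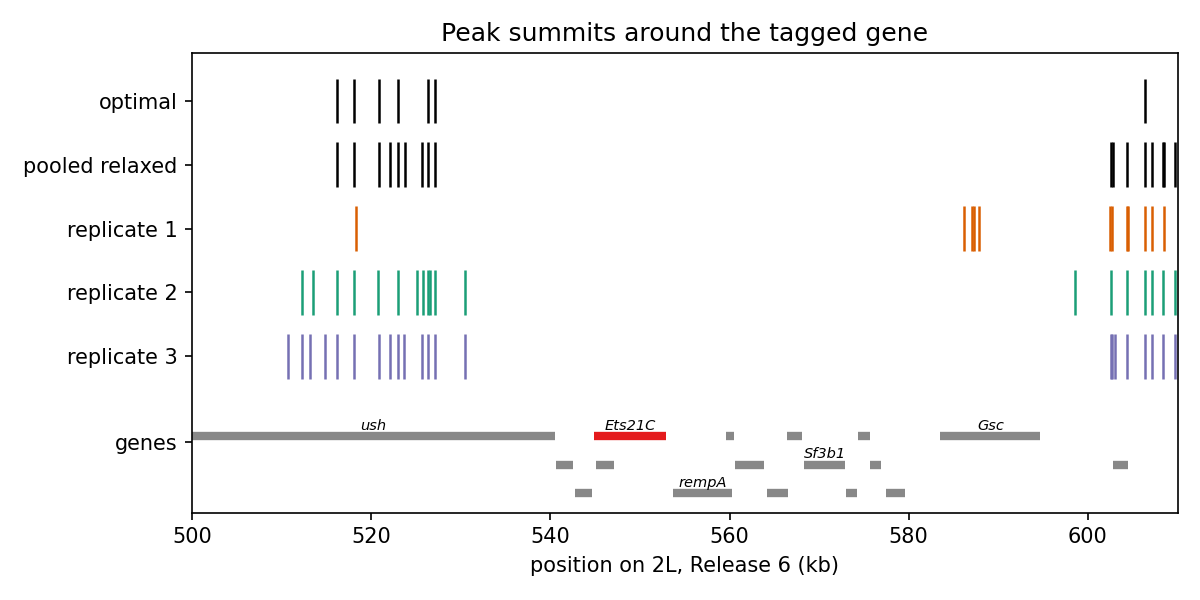
Peaks around Ets21C. Positions of the summits of the optimal, pooled and replicate lists, with genes below. The height of the marks does not show signal.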

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

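The region without peaks and the comparisons matched on base composition were chosen only after the data were seen, and the predictions for the 3 patterns here were written before their tests were run, except that on copies or a filter. The optimal list held 23 mitochondrial peaks (signals 222 to 3321), which stood out because the gene and word analyses left them without a result. The dm3 list held 1, and a count of 0 would have set a limit of 3. The top lists of replicates 1, 2 and 3 held 26, 26 and 21 on Release 6, against 5, 6 and 2 in their whole dm3 lists. The count thus depended on the build in each replicate, and the cause was not tested.

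Optimal summits were AT-rich and seldom held CCGGAAGY. A bias in base composition could by itself place peaks there, but promoters held 25.3 percentage points more of the optimal summits than of positions matched on composition (40.3% against 15.0%), which was against it. That AT-rich sequence leaves little room for the word was in line with its share of 0.366% at matched positions, within the interval of 0.155 to 0.496% at optimal summits, though on 13 peaks only. It did not account for the core MGGAAR, at 28.2% of optimal summits against 33.2% of matched positions (Fisher's exact adjusted p = 5.83e-10). That summits lie beside the word was not borne out: its share just outside the summit window minus that in a farther ring of the same width was −0.402 points (exact McNemar p = 0.0356).

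Replicate 1 had fewer promoter peaks in its top list (26.1%) than replicates 2 and 3. A top list that reaches into weak peaks was in line with the 500 highest peaks of replicate 1, whose promoter share differed by −2.6 points from the lower of the others. Weighting replicate 1 to the base composition of the others left its share at 26.2%, against 43.9% in replicate 2, so composition did not account for it. Ribosomal protein promoters could lie just below its top list, but its whole list had peaks at only 12 of them, against 35 in the top list of replicate 2 (Fisher's exact p = 1.57e-04).

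No list had a peak within 8 kb of Ets21C, and the pooled list had none in 2L:527324-602339. Of random windows with as many genes 1.03% (27 of 2612) were as empty, but the window length was set by the gap itself. Chance therefore stays open: counting this one, the genome had 59 gaps as long or longer, 6 of them with as many genes. These gaps held few genes, however: 259 of 13968 coding genes (1.85%) lay in the 59, and 217 (1.55%) in the 6. A coding gene named in advance, as Ets21C was, would seldom lie in one. Repeated sequence was ruled against by 0.0413% of the 36-base words of the gap around Ets21C lying elsewhere in the genome. Copies of the region in the control, or a filter on it, could also leave it empty: all 3 replicates lacked peaks within 8 kb of Ets21C, though each had peaks elsewhere in the region, and the lists alone cannot tell these apart. The peaks in ush at 2L:530428 (peak 108 of replicate 2) and 2L:530432 (peak 95 of replicate 3) lay inside the pooled gap. At that place the lack of a pooled peak was not a lack of signal in those replicates. No biological explanation was tested for any of the 3 patterns.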

How the results depend on the processing

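Alternatives were fixed before the data were examined, except those matched on base composition, with mitochondrial peaks kept, or with promoter heights over peaks found in all replicates, which were chosen after. Of 73 alternative values of 11 results, 57 kept their reading, and where no reason is given the cause was not tested. The part of the list with higher signal, shorter by construction, had 2252 optimal peaks and 1287 genes with a promoter peak. Without 1 replicate the gene count was 828 to 1511. The lists that passed numbered 4 with a TSS window of 250 bp, 13 with 1000 bp, 15 with gene bodies and 2 kb upstream, 4 among genes with a relaxed peak, 4 in the part with higher signal, and 1 to 6 without 1 replicate. The difference for the ETS word was −0.62 points with a window of 250 bp (exact p = 0.00877) and −6.05 for MGGAAR (exact p = 2.69e-09). Peaks with the word were 60.3 higher in signal with a window of 50 bp and 0.327 higher with MGGAAR. Within 50 kb Ets21C had 6 optimal peaks.

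Lists that changed direction (fold) were, with 250 bp, Toll 0.988, Wnt and Hedgehog 1.13, ETS family 0, fat body 0.944 and muscle 0.653. With 1000 bp it was Dpp 1.53. With gene bodies, not adjusted for gene length, they were JAK-STAT 1.75, Wnt and Hedgehog 1.84, Dpp 2.50, haemocyte 1.16 and vacuolar ATPase 0.900. Among genes with a relaxed peak they were Toll 0.804, muscle 0.965, epidermis 0.938 and Osiris 1.21. Matched on TSS number and gene length they were ETS family 0.993 and muscle 0.555. In the part with higher signal they were Wnt and Hedgehog 1.09, muscle 0.835 and vacuolar ATPase 0.987. Matched on base composition near a TSS they were Toll 0.971 and muscle 0.936. Without 1 replicate the folds were cytosolic ribosomal proteins 0.555 to 2.25, Toll 0.784 to 1.08, Wnt and Hedgehog 0.924 to 1.69, ETS family 0 to 1.16, fat body 0.937 to 1.72, muscle 0.711 to 1.30, epidermis 0.674 to 1.48, vacuolar ATPase 0.511 to 1.12, P450 0.434 to 1.19 and Osiris 0.739 to 1.35. Against positions matched on base composition, words changed direction in percentage points: rearranged ETS letters 1 0.0491 and 2 0.00893, GAGA 0.599, E-box 0.357, Brinker 0.0581 and Scalloped 0.0893, and, of words that had not passed, STAT −1.22, rearranged ETS letters 3 0.237, AP-1 0.0893 and NF-kB 0.241.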

Other observations

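The values in this part were looked for only after the results were seen. Many optimal peaks lay in single genes, counted over the gene and 2 kb upstream: 24 in kirre (0.606 per 10 kb), 19 in CG1677 (a gene of 124709 bp), 17 in sbb (2.10 per 10 kb), 16 in CG43658 (105012 bp), 15 in Mnt (4.71 per 10 kb), 14 in shn (2.32) and 13 in Raf (2.58). Long genes have more room for peaks, so the order by count is not one of density. Of 3292 genes with any, 134 had 5 or more. The whole list of replicate 3 had 21.9% of its peaks on X, against 13.6% and 13.4% in replicates 1 and 2, and 22.3% against 12.7% below the top lists. Among shared peaks the median log2 ratio of replicate 3 to the others was 0.26 higher on X (95% bootstrap interval 0.20 to 0.30, from resampled peaks). The ratio was 4.56e-04 on X and −0.262 on the other arms, with each replicate scaled to its own top list. A prediction that heights in replicate 3 were raised on X relative to the other arms was written before its test. It was met, but in the same lists that had shown the higher X share. Another, that the excess lay among weak calls, was written after the values were seen, so its fit is no support. Both were set aside to keep to 3 patterns and are not weighed here. Of 740 peaks shared by the top 1000 of replicates 2 and 3, 9 had no pooled peak within 500 bp, those in ush among them.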
